A study of Homo sapiens with 16 samples.

How the data were processed

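MIA PaCa-2 is an established human pancreatic cancer cell line. Per the labels, its cells were treated for 48 h with 0.3 µM pyrvinium pamoate, 4 µM oligomycin or 0.5 µM rotenone, or were DMSO controls, with 4 samples in each of the 4 groups and 16 in all. Oligomycin blocks the mitochondrial ATP synthase and rotenone blocks complex I of the respiratory chain. Pyrvinium is an anthelmintic dye that collects in mitochondria. The labels do not say whether the 4 samples of a group were separate cultures, so the p-values measure the spread between these samples.

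For each sample the authors deposited a file of read counts per gene and a file of FPKM (fragments per kilobase of gene and per M of counted reads, where M stands for mega). The deposited count values were whole numbers. The deposited FPKM equalled the count divided by the gene length and by the total of the count file, to within a difference of 4.03e-06. The submitters' processing notes name CASAVA, bcl2fastq, STAR 2.5, HTSeq 0.6.1 and the genome build GRCh38.p5, without their roles. The gene coordinates in the files do not match that build: of 45329 nuclear gene identifiers shared with GENCODE release 29, which is on GRCh38, 0.69% had the same start or end. Positions are therefore given as the files print them, with the build left open. The files held 48162 genes, 20312 of them protein coding, with 13 genes of mitochondrial DNA, all protein coding, and no genes typed as rRNA, tRNA, snRNA, snoRNA or miRNA. Whether the libraries were stranded is not stated. DDIT3, MT-ATP8, NDUFA1, MCM2, GINS2, KIF20A, SQSTM1, BIRC5, AXIN2, CCND1, PCK2, FDFT1, LIF, PIK3R3, FADS2, IFITM1, FTH1, WIPI1, HJURP, CCRN4L, NCSTN and GSN overlap another protein-coding gene in these coordinates, so their counts also depend on how shared reads were assigned.

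Total counts per library ranged from 23.7 to 41.4 M. The mean was 36.8 M in DMSO, 27.3 M with pyrvinium, 24.7 M with oligomycin and 25.3 M with rotenone. Shares of counts in single libraries carry 95% Wilson intervals, and these cover counting error only. No library was a copy of another of its group.

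Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, TMM scaling, filterByExpr filter), with all 16 libraries in 1 fit of 4 group means. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and 15674 genes were tested. Errors of log2 fold changes are SEs, computed as the size of the log2 fold change over the square root of F. Normalised counts (CPM, counts per M) are after TMM scaling. Gene lists were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset correlation between genes of 0.01. The adjustment was over the 36 lists with at least 5 tested members and all 6 comparisons. Camera with an estimated correlation and fry were alternatives. The share of counts on mitochondrial DNA was compared with a two-sided exact permutation test, for which the smallest p with 4 against 4 libraries is 0.0286.

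The 37 lists were fixed before the data were examined, as were the main tests, the comparisons, the rule for named genes and most alternatives. The lists cover respiratory chain subunits encoded in mitochondrial DNA, nuclear subunits of complex I, of complexes III and IV and of ATP synthase, the mitochondrial ribosome, expression of mitochondrial DNA, mitochondrial proteostasis, the TCA cycle and glycolysis. They further cover integrated stress response targets of ATF4, serine and one-carbon metabolism, cytosolic tRNA synthetases, the unfolded protein response of the endoplasmic reticulum, cholesterol synthesis, fatty acid synthesis, nucleotide synthesis, and targets of WNT, HIF, NRF2, NF-κB, interferon and MAPK signalling. The remaining lists are immediate early genes, DNA replication, mitosis, replication histones, ribosome biogenesis, the cytosolic ribosome, autophagy and lysosome, BCL2 family and cell death, tubulins, mesenchyme and matrix, pancreatic differentiation, and markers of fibroblasts, immune cells and endothelium. Of the 37 lists 1 is not reported here, nor are some single genes. Of 964 list entries 963 matched a gene in the files. Named genes were the 8 largest rises and 8 largest falls per compound against DMSO, or 4 and 4 between compounds, among called protein-coding genes with a mean of at least 5 CPM in 1 group and no overlap between the groups. The rule also took the 13 genes of mitochondrial DNA, the 4 members of each list with the smallest p, and ELAVL1, MYC, ATF4, DDIT3, AXIN2, CCND1, CDKN1A, VIM, TFAM and TUBB. The text names part of what the rule allows.

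Alternatives were RLE scaling, scaling without genes of mitochondrial DNA, library totals only, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 0.1 and 1, no filter, a filter of at least 10 counts in 4 libraries, only the 8 libraries compared, the replicate number as a block, and each library left out in turn. The labels name no pairs, and replicate numbers were treated as pairs only where residuals matched by number. In pyrvinium against rotenone, residuals of libraries with the same number correlated across genes at 0.374 to 0.626 and the own number was the best match in 4 of 4 cases. In the other 5 comparisons at least 2 of the 4 numbers failed this check. With the replicate number as a block, pyrvinium against rotenone called 1660 genes.

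Within groups, 51.7% of the variance lay on 1 component whose gene loadings correlated with GC content (Pearson's r 0.774 across genes, which are not independent replicates). The trend of counts with GC content ranged from a slope of 0.84 log2 units per 10 points of GC in pyrvinium replicate 1 to -0.67 in pyrvinium replicate 4, while group means lay between -0.03 and 0.02. After seeing this, a spline of each library on GC content with 5 degrees of freedom was added as an offset, over the 97.0% of tested genes with a GC value. A GC slope covariate and a fit without the 3 libraries of slopes over 0.5 were added too. In 1 simulated data set 200 genes changed per compound, and the GC trends of the 16 libraries were dealt out at random. There the main test recovered 54.5 to 56.1% of 4-fold changes, 4.48 to 10.4% of 2-fold changes and 0% of 1.5-fold changes, with at most 1 false call per comparison. With the GC offset it recovered 23.9 to 40.3% of 2-fold changes with at most 5 false calls. A single data set gives no rate of false calls. In 20 further draws with no effect, false calls shared by oligomycin and rotenone reached 212 in 1 draw.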

Results

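RNA sequencing measured gene expression in 16 libraries of MIA PaCa-2 pancreatic cancer cells after 48 h with DMSO, pyrvinium pamoate, oligomycin or rotenone, 4 libraries per group. Libraries held 23.7 to 41.4 M (mega) counts. The comparisons ask how the transcriptome of these cells responds to pyrvinium, and how that response stands beside those to inhibitors of the ATP synthase and of complex I. The doses differ between compounds, so the sizes of their effects are set side by side at the doses used. A value such as 2.14 ± 0.30 for ATF4 with pyrvinium is a log2 fold change against the group compared, with its SE, from 4 libraries per group. Within groups the libraries differed in the trend of their counts with GC content, from a slope of 0.84 log2 units per 10 points of GC in pyrvinium replicate 1 to -0.67 in pyrvinium replicate 4, while the group means lay between -0.03 and 0.02.

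**Figure D1:**
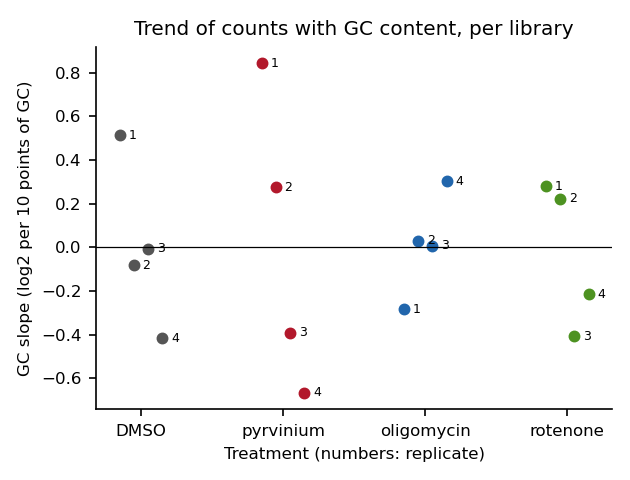
Slope of each library's counts on GC content (log2 units per 10 points of GC) by treatment, numbered by replicate. Points are libraries, 4 per group, and the spread within groups exceeds the differences between group means.

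The share of counts on the 13 genes of mitochondrial DNA was 2.72 ± 1.01% in DMSO (mean ± SD, n = 4). With pyrvinium it was 0.208 ± 0.177% (n = 4), a fall of 13.1-fold, and each pyrvinium library lay below each DMSO library (exact permutation p = 0.0286, the smallest possible, and 0.0857 adjusted over 3 compounds). The lowest pyrvinium library held 0.0340% (95% Wilson interval 0.0333 to 0.0346%) and the highest 0.383% (0.381 to 0.386%). With oligomycin the share was 2.84 ± 2.33% (n = 4, exact permutation p = 0.971) and with rotenone 1.88 ± 0.485% (n = 4, exact permutation p = 0.171), so neither passed the test. The difference of oligomycin from DMSO, 0.12 points, turned to -0.87 without oligomycin replicate 1, -0.118 without oligomycin replicate 3, -0.116 without DMSO replicate 1 and -0.203 without DMSO replicate 3.

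**Figure D2:**
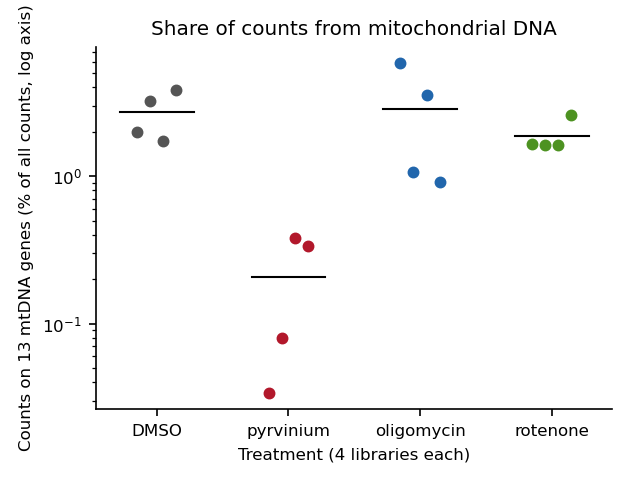
Share of each library's counts on the 13 genes of mitochondrial DNA, in percent on a log axis, for the 4 treatments. Points are libraries and lines are group means. The 4 pyrvinium libraries lie between 0.0340 and 0.383%, below all others.

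Pyrvinium raised transcripts of targets of the integrated stress response and lowered transcripts of mitochondrial DNA and genes of DNA replication. Among targets of ATF4, the transcription factor of that response, 32 of 36 measured members rose and 1 fell (list adjusted p = 5.86e-23, and adjusted p = 0.157 with an estimated correlation). Log2 fold changes were 8.06 ± 1.12 for GDF15, 6.51 ± 0.57 for NUPR1, 5.12 ± 0.58 for DDIT3 and 3.84 ± 0.40 for CHAC1, with adjusted p between 1.59e-05 and 2.83e-04. GDF15 is a secreted stress cytokine, NUPR1 and DDIT3 are stress-induced nuclear regulators and CHAC1 degrades glutathione. NUPR1 went from 0.534 ± 0.234 CPM in DMSO to 49.1 ± 26.4 CPM (SD, n = 4), and DDIT3 from 1.77 ± 0.337 to 61.7 ± 41.6 CPM. Of the 4 pyrvinium libraries replicate 3 lay nearest the DMSO mean in 23 of the 33 members called in this list and in 1425 of all 2716 called genes. ATF4 itself rose by 2.14 ± 0.30 and ATF3 by 5.18 ± 0.63 (adjusted p between 1.49e-04 and 2.81e-04). LAMP3, a lysosomal membrane protein outside the list, rose by 7.43 ± 0.66 from 0.122 ± 0.0709 CPM in DMSO. In serine and one-carbon metabolism 8 of 18 members rose, among them PHGDH, the first enzyme of serine synthesis, at 1.76 ± 0.27, and 4 fell (list adjusted p = 0.0349, and adjusted p = 0.408 with an estimated correlation). Of cytosolic tRNA synthetases 5 of 20 rose, such as CARS (adjusted p = 2.81e-04), and 1 fell, and that list did not pass (list adjusted p = 0.165). The files place these genes as NUPR1 (ENSG00000176046, chromosome 16, 28548606 to 28550495) and DDIT3 (ENSG00000175197, chromosome 12, 57910371 to 57914300).

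Of the 13 transcripts of mitochondrial DNA, 12 fell with pyrvinium, with a median log2 fold change of -4.03 (list adjusted p = 2.52e-12, and adjusted p = 0.242 with an estimated correlation). MT-CYB (ENSG00000198727, chromosome MT, 14747 to 15887), the cytochrome b of complex III, fell by 4.62 ± 0.67 on the log2 scale, from 1837 ± 732 to 74.9 ± 53.8 CPM. MT-ND1 of complex I fell by 3.29 ± 0.62. MT-ATP8 did not pass, at -1.75 ± 1.23 (adjusted p = 0.371). It overlaps MT-ATP6 on the same strand and held a mean of 1.09 against 934 CPM over library totals, so its count depends on how shared reads were assigned. Nuclear subunits fell less, with medians of -0.59 for complex I (7 of 37 fell), -0.73 for complexes III and IV (6 of 21) and -0.81 for ATP synthase (7 of 16), and no member was called higher. ATP5G1, a membrane subunit of ATP synthase, had -1.97 ± 0.33 and NDUFA1 of complex I -1.40 ± 0.30. The mitochondrial ribosome (11 of 75 fell), the TCA cycle (7 of 21, with IDH2 at -1.27 ± 0.26) and mitochondrial proteostasis (5 fell and 1 rose of 23) were called lower as well. For these 6 nuclear lists there was a list adjusted p between 3.53e-08 and 0.0209, and adjusted p between 0.249 and 0.353 with an estimated correlation. Genes that transcribe and process mitochondrial RNA did not pass as a list (2 of 28 fell, list adjusted p = 0.0501), and were called lower with the replicate block (0.0400) and with the GC offset (0.0105), but not with an estimated correlation (0.526). TFAM, which packages mitochondrial DNA, had -0.09 ± 0.45 (adjusted p = 0.923), a value that turned to 0.02 with library totals only and 0.36 without DMSO replicate 4. In glycolysis 9 of 24 members fell, such as PGAM1 at -1.34 ± 0.22, while 2 rose, among them HK2 at 1.56 ± 0.34 (list adjusted p = 0.00162, and adjusted p = 0.341 with an estimated correlation).

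Genes of proliferation and of sterol and nucleotide synthesis fell with pyrvinium. In DNA replication 33 of 44 members fell and none rose (list adjusted p = 3.19e-21, and adjusted p = 0.238 with an estimated correlation), with -1.98 ± 0.34 for MCM2 and -2.72 ± 0.47 for GINS2, both parts of the replicative helicase. Of mitosis genes 15 of 36 fell and none rose (list adjusted p = 3.06e-12, and adjusted p = 0.318 with an estimated correlation), among them the kinesin KIF20A at -2.21 ± 0.41. In nucleotide synthesis 8 of 22 fell (list adjusted p = 3.62e-06, and adjusted p = 0.318 with an estimated correlation), with thymidine kinase TK1 at -2.40 ± 0.32. Cholesterol synthesis was the 1 list whose call held with an estimated correlation (13 of 23 fell, none rose, list adjusted p = 1.58e-10, and adjusted p = 0.00527 with an estimated correlation). Its enzyme HSD17B7 had -2.17 ± 0.22. In fatty acid synthesis 6 of 15 fell (list adjusted p = 5.00e-04, and adjusted p = 0.190 with an estimated correlation). Of tubulins, the subunits of microtubules, 7 of 15 fell (list adjusted p = 5.08e-05, and adjusted p = 0.190 with an estimated correlation), with -1.71 ± 0.25 for TUBB2A and -1.15 ± 0.23 for TUBB. In ribosome biogenesis 3 of 34 fell (list adjusted p = 0.00320, and adjusted p = 0.380 with an estimated correlation), and the cytosolic ribosome did not pass (2 rose and 3 fell of 53, list adjusted p = 0.105), but was called lower with the replicate block (0.0497) and in 3 of the 8 fits with 1 library left out.

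Several stress and signalling lists were called higher with pyrvinium, and WNT targets and interferon genes lower. The cell cycle inhibitor CDKN1A had 4.83 ± 0.73, SESN2, of the ATF4 list, 3.87 ± 0.45, and the pro-apoptotic BBC3 3.13 ± 0.45 (adjusted p between 1.05e-04 and 4.82e-04). In the BCL2 family and cell death list, which holds BBC3, 10 of 23 rose and none fell (list adjusted p = 1.08e-04, and adjusted p = 0.249 with an estimated correlation), with HRK at 3.94 ± 0.36. Of NRF2 targets, antioxidant genes, 9 of 23 rose (list adjusted p = 4.25e-05, and adjusted p = 0.247 with an estimated correlation), with heme oxygenase HMOX1 at 4.43 ± 0.66. In autophagy and lysosome 10 of 31 rose and 1 fell (list adjusted p = 8.88e-04, and adjusted p = 0.443 with an estimated correlation), with the autophagy receptor SQSTM1 at 3.48 ± 0.51. SQSTM1 is also a member of the ATF4 list. Immediate early genes (11 of 22 rose), MAPK output (8 of 23) and NF-κB targets (7 of 17 rose and 1 fell, with RELB at 2.66 ± 0.36) were called higher, with list adjusted p between 7.16e-06 and 7.25e-04 and adjusted p between 0.174 and 0.318 with an estimated correlation. WNT targets were called lower (6 of 16 fell, list adjusted p = 0.00380, and adjusted p = 0.249 with an estimated correlation), with -1.66 ± 0.30 for BIRC5 and -1.38 ± 0.27 for CD44, of which BIRC5 is also a mitosis gene. The WNT feedback gene AXIN2 and the cyclin CCND1 did not pass, at -0.19 ± 0.55 and -0.57 ± 0.42, and neither did MYC at 0.11 ± 0.17, ELAVL1, which encodes the RNA-binding protein HuR, at -0.29 ± 0.16 or VIM at -0.08 ± 0.45. AXIN2 turned to 0.20 without DMSO replicate 1 and to 0.00 without DMSO replicate 3, MYC to -0.01 without pyrvinium replicate 1, and VIM to 0.02 with library totals only and 0.24 without pyrvinium replicate 1.

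Interferon response genes were called lower (4 of 23 fell, list adjusted p = 0.0123, and adjusted p = 0.449 with an estimated correlation). In the unfolded protein response ERN1, its sensor, rose by 2.68 ± 0.32 and the chaperone CALR fell by 1.20 ± 0.19 (5 rose and 5 fell of 26, list adjusted p = 0.852). In pancreatic differentiation the transcription factor HNF4A rose from at most 0.0548 CPM in DMSO, under a floor of 3 counts, to between 0.643 and 7.15 CPM (adjusted p = 2.78e-04), and the keratin KRT19 fell by 1.82 ± 0.29 (3 and 3 of 12, list adjusted p = 0.656). Collagen COL1A2, which this line expresses and which the mesenchyme and fibroblast lists share, fell by 2.58 ± 0.42. Mesenchyme and matrix (3 rose and 4 fell of 30), replication histones (2 and 2 of 12), fibroblast markers (1 and 2 of 5) and endothelial markers (1 and 0 of 7) did not pass, with list adjusted p between 0.195 and 0.924, and immune markers had too few expressed members for a test. HIF targets did not pass (4 of 23 rose, list adjusted p = 0.147).

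In all, 2716 genes differed between pyrvinium and DMSO, 1585 higher and 1131 lower, and 26 of 36 lists were called. Of the 25 reported here 21 were called with each library left out. Serine and one-carbon metabolism lost its call without DMSO replicate 1 or pyrvinium replicate 3 or 4 and with the GC offset (adjusted p = 0.0530), mitochondrial proteostasis without pyrvinium replicate 1, and WNT targets and interferon genes without DMSO replicate 1. Of lists that did not pass, tRNA synthetases and replication histones were called in 1 of these 8 fits and expression of mitochondrial DNA in 3. Adjusted over the list alone, 33 ATF4 targets rose and 36 replication genes, 12 mitochondrial DNA transcripts and 14 cholesterol genes fell. The count was 1730 without DMSO replicate 2, 1712 without DMSO replicate 3 and 1777 without pyrvinium replicate 2, 1103 with only the 8 libraries compared and 4836 with the GC offset. The 37 named genes that passed did so with each library left out. The median of all genes was 0.10 with TMM and 0.17 with library totals only.

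**Figure D3:**
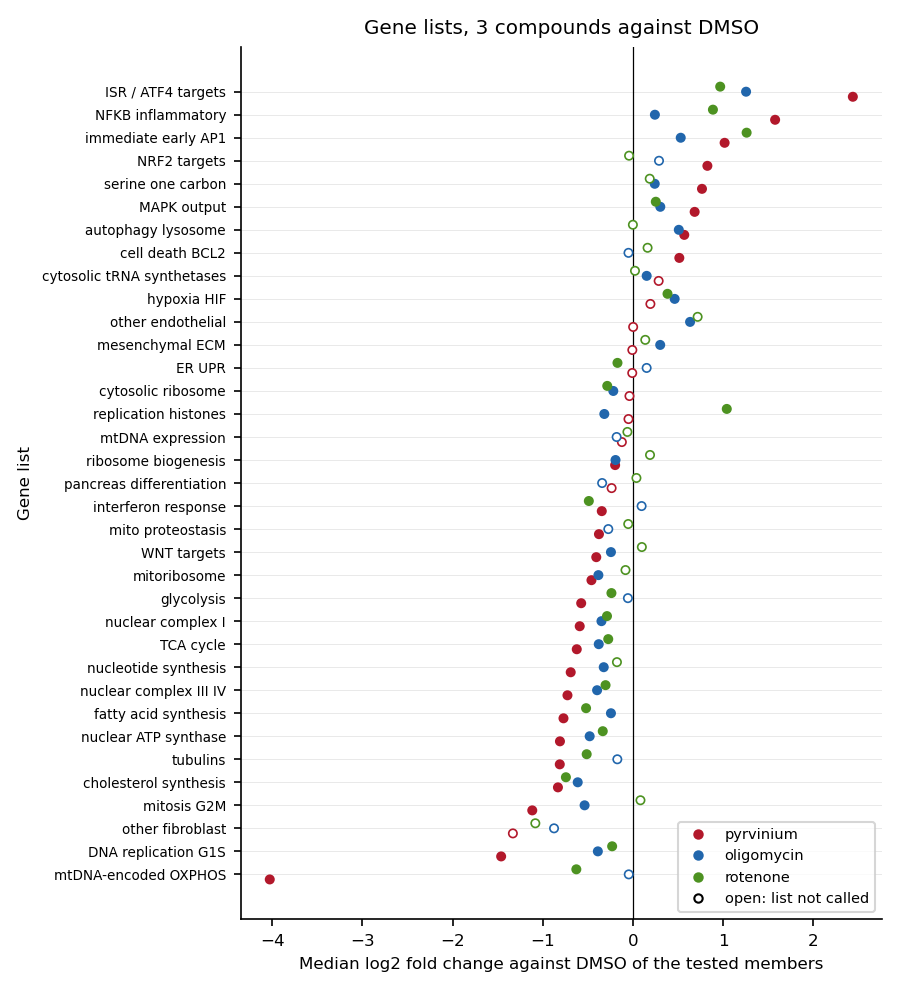
Median log2 fold change against DMSO of the tested members of each gene list reported, for pyrvinium, oligomycin and rotenone (4 libraries each). Filled points are lists called with a preset correlation and open points are not called. The list of mitochondrial DNA transcripts lies at -4.03 with pyrvinium and at -0.05 and -0.63 with oligomycin and rotenone, where the value for oligomycin ranged from -0.65 to 0.23 with 1 library left out.

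Oligomycin raised targets of the integrated stress response. Of ATF4 targets 8 of 36 rose and none fell, and 27 rose adjusted over the list alone (list adjusted p = 6.88e-23, and adjusted p = 0.157 with an estimated correlation), with 2.62 ± 0.49 for NUPR1, 1.76 ± 0.30 for JDP2, 2.08 ± 0.37 for VLDLR and 2.04 ± 0.42 for SESN2. ATF4 and DDIT3 had 1.08 ± 0.29 and 2.24 ± 0.51 and passed only adjusted over the list alone (adjusted p = 0.175 and 0.0913 over all genes). In serine and one-carbon metabolism PHGDH (1.77 ± 0.27) and PCK2 (1.45 ± 0.24) rose, 2 of 18 members and 6 adjusted over the list alone (list adjusted p = 0.00290, and adjusted p = 0.289 with an estimated correlation). PHGDH reached 338 ± 100 CPM, from 99.1 ± 9.75 CPM in DMSO (SD, n = 4). CARS, a tRNA synthetase held by 2 lists, rose by 1.01 ± 0.21, as 1 of 20 synthetases (list adjusted p = 0.0169, and adjusted p = 0.408 with an estimated correlation), a list call lost without DMSO replicate 1 or oligomycin replicate 2, 3 or 4.

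Large rises included 3.28 ± 0.51 for FAM129A, 2.70 ± 0.47 for UNC5B, 2.64 ± 0.36 for OSBPL6, 2.33 ± 0.39 for VGF and 2.22 ± 0.35 for SLC1A4, with adjusted p between 0.0178 and 0.0226. FAM129A, also called NIBAN1, responds to endoplasmic reticulum stress, UNC5B is a netrin receptor and SLC1A4 carries neutral amino acids. VEGFA, the vascular growth factor, rose by 2.05 ± 0.38 as 1 of 23 HIF targets (list adjusted p = 0.00220, and adjusted p = 0.238 with an estimated correlation). HBEGF, a ligand of the EGF receptor, rose by 1.44 ± 0.25 in the MAPK output list (list adjusted p = 8.88e-04, and adjusted p = 0.174 with an estimated correlation). The cytokine LIF rose by 1.48 ± 0.30 among NF-κB targets (list adjusted p = 0.0292, and adjusted p = 0.404 with an estimated correlation), a list call lost without DMSO replicate 4 or oligomycin replicate 3. HRK rose by 1.90 ± 0.34, while its cell death list did not pass (list adjusted p = 0.821). AFAP1L2, an actin filament-associated protein, fell by 2.33 ± 0.36 and PIK3R3, a regulatory subunit of PI3-kinase, fell by 1.27 ± 0.19.

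Cholesterol synthesis fell with oligomycin too, and this call held with an estimated correlation (list adjusted p = 5.12e-10, and adjusted p = 0.00527 with an estimated correlation). FDFT1, squalene synthase, fell by 0.80 ± 0.15 as the 1 member called over all genes, and 10 of 23 fell adjusted over the list alone, among them INSIG1 at -1.16 ± 0.27 (adjusted p = 0.0989 over all genes). The lists of complex I, complexes III and IV, ATP synthase, the mitochondrial ribosome, the TCA cycle, DNA replication, mitosis, nucleotide synthesis and the cytosolic ribosome were called lower with medians between -0.54 and -0.22 and no member called (list adjusted p between 9.32e-09 and 0.00367, and adjusted p between 0.318 and 0.568 with an estimated correlation). Oligomycin replicate 1 lay apart in such genes, with MCM2 at 139 against 420 to 471, GINS2 at 11.8 against 48.0 to 54.6 and TK1 at 79.8 against 216 to 251 CPM in the other 3 libraries. Without it 20 of the 24 list calls held, and DNA replication had a median of -0.14 (adjusted p = 0.00895). The calls of nucleotide synthesis (adjusted p = 0.194), the cytosolic ribosome (adjusted p = 0.181), WNT targets and ribosome biogenesis were lost. Autophagy and lysosome and immediate early genes were called higher, also with no member called (list adjusted p between 8.71e-06 and 3.98e-04, and adjusted p between 0.318 and 0.408 with an estimated correlation). Endothelial markers were called higher with no member called of 7 (list adjusted p = 0.0383, and adjusted p = 0.403 with an estimated correlation), and not called without DMSO replicate 2, 3 or 4 or oligomycin replicate 3 or 4. Transcripts of mitochondrial DNA had a median of -0.05, with MT-CYB at -0.36 ± 0.58 (adjusted p = 0.899), and did not pass as a list (list adjusted p = 0.131). With 1 library left out the median ranged from -0.65 to 0.23, and the list was called lower without oligomycin replicate 1 (adjusted p = 1.22e-04) or 3 (0.0213) or DMSO replicate 3 (0.0221).

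Oligomycin and DMSO differed in 51 genes, 45 higher and 6 lower, and in 24 lists, of which 15 were called with each library left out. The count was 0 in edgeR without DMSO replicate 2, 3 or 4 (1105, 1087 and 1207 genes at an unadjusted p under 0.05), 8 without oligomycin replicate 1 or 3 and 1 without oligomycin replicate 4. Each of the 19 named genes that passed lost its call without at least 1 library. With all libraries DESeq2 called 228 genes, limma-voom 21 and edgeR with the GC offset 263 (155 higher and 108 lower, or 58.9% higher against 88.2%).

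Rotenone raised immediate early genes. Of that list 9 of 22 members rose and none fell, and 13 rose adjusted over the list alone (list adjusted p = 8.49e-16, and adjusted p = 0.174 with an estimated correlation). The transcription factors ATF3, EGR1 and FOS had 4.05 ± 0.60, 2.64 ± 0.37 and 2.33 ± 0.42 (adjusted p between 0.00312 and 0.0118). ATF3 is also a member of the ATF4 list. EGR4, outside the list, had 4.26 ± 0.61. EGR1 went from 42.6 ± 19.3 CPM in DMSO to 266 ± 27.8 CPM (SD, n = 4). In MAPK output 4 of 23 rose (list adjusted p = 1.11e-04, and adjusted p = 0.125 with an estimated correlation), with 1.66 ± 0.25 for HBEGF and 2.29 ± 0.38 for DUSP5, the second a phosphatase of ERK.

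Of ATF4 targets 6 of 36 rose with rotenone, and 20 adjusted over the list alone (list adjusted p = 8.12e-12, and adjusted p = 0.238 with an estimated correlation), with 2.63 ± 0.52 for DDIT3, 2.02 ± 0.43 for TRIB3 and 1.95 ± 0.42 for SESN2. ATF4 itself had 0.96 ± 0.29 (adjusted p = 0.148). GADD45A, a stress gene, rose by 3.08 ± 0.53. GLDC (ENSG00000178445, chromosome 9, 6532464 to 6645650), the glycine decarboxylase of mitochondria, rose by 2.72 ± 0.28 from 5.76 ± 0.737 to 37.9 ± 3.74 CPM, while its serine and one-carbon list did not pass (list adjusted p = 0.101). Replication histones were called higher (2 of 12 rose, 5 adjusted over the list alone, list adjusted p = 6.64e-06, and adjusted p = 0.249 with an estimated correlation), with 2.83 ± 0.35 for HIST1H2BC and 1.82 ± 0.37 for HIST2H2BE. Among NF-κB targets TNFAIP3, an inhibitor of that pathway, rose by 2.61 ± 0.35 (list adjusted p = 7.02e-04, and adjusted p = 0.245 with an estimated correlation). Among HIF targets the peptide hormone ADM rose by 2.30 ± 0.35 (list adjusted p = 0.00219, and adjusted p = 0.238 with an estimated correlation). CYR61, a matrix protein, rose by 1.71 ± 0.28.

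Lipid synthesis fell with rotenone. Of cholesterol synthesis genes 4 of 23 fell, and 10 adjusted over the list alone (list adjusted p = 1.49e-15, and adjusted p = 0.00165 with an estimated correlation), with -0.94 ± 0.16 for FDFT1 and -1.47 ± 0.28 for INSIG1. In fatty acid synthesis the desaturases FADS2 and SCD fell, at -1.45 ± 0.24 and -1.55 ± 0.28, 2 of 15 members and 4 adjusted over the list alone (list adjusted p = 9.53e-08, and adjusted p = 0.0351 with an estimated correlation). SCD went from 1813 ± 300 to 620 ± 76.4 CPM. Interferon response genes were called lower (1 of 23 fell, 7 adjusted over the list alone, list adjusted p = 1.03e-07, and adjusted p = 0.210 with an estimated correlation), with IFITM1 at -2.15 ± 0.39, and its relative IFITM3 had -1.56 ± 0.36. In the unfolded protein response the disulfide isomerase PDIA4 fell by 0.71 ± 0.16 (list adjusted p = 0.0292, and adjusted p = 0.429 with an estimated correlation). Tubulins were called lower with no member called over all genes (list adjusted p = 4.37e-04, and adjusted p = 0.238 with an estimated correlation), TUBB2A having -0.96 ± 0.24 (adjusted p = 0.0759). Transcripts of mitochondrial DNA were called lower as a list (list adjusted p = 0.0103, and adjusted p = 0.583 with an estimated correlation) with no member called and a median of -0.63, MT-CYB having -0.63 ± 0.58. Complex I, complexes III and IV, ATP synthase, the TCA cycle, DNA replication, glycolysis and the cytosolic ribosome were called lower with medians between -0.33 and -0.23 and no member called (list adjusted p between 5.52e-06 and 0.0214, and adjusted p between 0.318 and 0.640 with an estimated correlation).

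Rotenone and DMSO differed in 159 genes, 120 higher and 39 lower (75.5% higher, against 90.3% with library totals only and 45.0% of the 615 genes with the GC offset), and in 19 lists. Of these 15 were called with each library left out. Transcripts of mitochondrial DNA lost their call without DMSO replicate 4, complexes III and IV without rotenone replicate 3, glycolysis without either DMSO replicate 1 or rotenone replicate 3, and the unfolded protein response in 4 of the 8 fits. Of lists that did not pass, the mitochondrial ribosome and ribosome biogenesis were called in 3 of these fits. Serine and one-carbon metabolism and nucleotide synthesis were called in 2 and expression of mitochondrial DNA in 1. Each left-out library lowered the count by more than 1.5 times, to 98, 38, 59 and 65 without DMSO replicates 1 to 4 and to 65, 49, 54 and 64 without rotenone replicates 1 to 4. DESeq2 called 455 genes, limma on log2(FPKM + 1) 246 and edgeR on only the 8 libraries compared 525. Of the 23 named genes that passed, 12 kept their call throughout. The calls of FOS, GADD45A, HIST2H2BE, DDIT3, TRIB3, SESN2, INSIG1, SCD, IFITM1, IFITM3 and PDIA4 were lost without at least 1 library. With library totals only the median of all genes was 0.14.

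**Figure D4:**
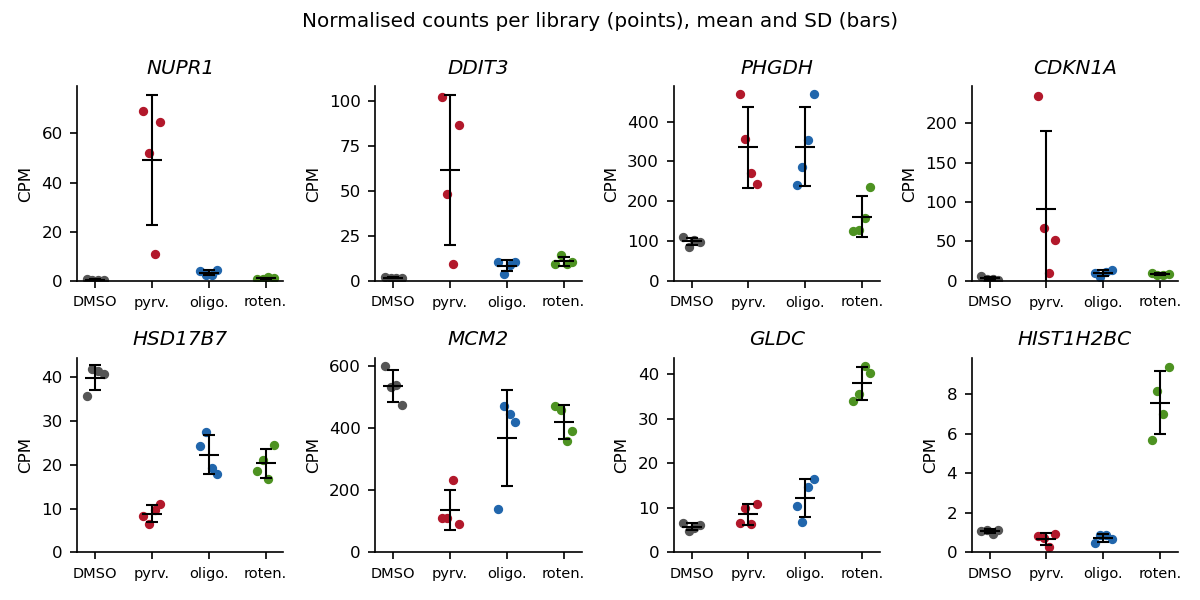
Normalised counts (CPM) of 8 genes in each library by treatment. Points are libraries, and black bars are means with SD, n = 4. The means of NUPR1 and DDIT3 are highest with pyrvinium, and those of GLDC and HIST1H2BC with rotenone.

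All 3 compounds changed 12 genes alike against DMSO, 9 higher and 3 lower. HBEGF and SESN2 rose with each compound and FDFT1 and AFAP1L2 fell with each. Independent lists of these sizes would share 0.0348 rises and 0.00108 falls. Pyrvinium and oligomycin shared 47 calls in 1 direction and none in opposite directions, pyrvinium and rotenone 99 and 1, and oligomycin and rotenone 14 and none. All comparisons used the same DMSO libraries. In 20 simulated draws with no effect of any compound the shared calls of a pair averaged 1.15, 0.70 and 10.6, and reached 23, 14 and 212. Genes called alike by all 3 averaged 0.70 and reached 14. All of these simulated shared calls came in 1 draw. The draws dealt the GC trends of the libraries out at random, so simulated groups could differ in GC trend. The real group means lay between -0.03 and 0.02, so the draws cannot tell whether shared controls alone give the 12. The log2 fold changes correlated across genes at 0.56 for pyrvinium and oligomycin, 0.52 for pyrvinium and rotenone and 0.53 for oligomycin and rotenone. The simulated draws averaged 0.55, 0.49 and 0.52 and reached 0.79, 0.78 and 0.80. The observed correlations lie within that range, which holds shared controls together with GC trends dealt out at random. With 2 DMSO libraries for each compound and none shared, the correlations averaged 0.35, 0.32 and 0.23 over the ways to split DMSO. They ranged from 0.23 to 0.45, 0.26 to 0.42 and 0.09 to 0.34. Shared calls of a pair under this split averaged 0.17, 2.17 and 0, and reached 1, 5 and 0. The split also leaves fewer DMSO libraries behind each fold change. Genes are not independent replicates, so no p-value is given.

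Set directly against oligomycin, pyrvinium had lower transcripts of mitochondrial DNA (12 of 13, median -3.88, list adjusted p = 2.16e-14, and adjusted p = 0.238 with an estimated correlation), with MT-CYB at -4.25 ± 0.66. ATF4 targets were higher with pyrvinium in 21 of 36 members and lower in 1 (list adjusted p = 7.05e-12, and adjusted p = 0.238 with an estimated correlation), with 5.69 ± 1.00 for GDF15, 3.89 ± 0.49 for NUPR1, 2.88 ± 0.52 for DDIT3 and 1.05 ± 0.29 for ATF4. PHLDA3, an inhibitor of AKT, had 4.15 ± 0.66, BBC3 of the cell death list 2.40 ± 0.43 (7 of 23 higher, list adjusted p = 9.24e-07, and adjusted p = 0.190 with an estimated correlation), and KLHDC7B, outside the lists, 4.21 ± 0.79. DNA replication genes were lower in 19 of 44 (list adjusted p = 1.24e-16, and adjusted p = 0.249 with an estimated correlation), with GINS2 at -2.12 ± 0.46. TK1 of nucleotide synthesis had -1.88 ± 0.32. Cholesterol synthesis (3 of 23 lower, with HSD17B7 at -1.32 ± 0.22), mesenchyme and matrix (5 of 30, with -2.06 ± 0.41 for COL1A2 and -1.76 ± 0.30 for TGFBI) and tubulins (6 of 15, with TUBB2A at -1.01 ± 0.24) were also lower, with list adjusted p between 4.70e-05 and 0.00315 and adjusted p between 0.120 and 0.318 with an estimated correlation. STC1, a secreted glycoprotein of the HIF list, had -2.04 ± 0.37, and that list did not pass (list adjusted p = 0.924).

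Pyrvinium and oligomycin differed in 1288 genes, 808 higher with pyrvinium and 480 lower (62.7% higher, against 48.6% with limma on log2(FPKM + 0.1)), and in 21 lists. Of the 20 reported here 12 were called with each library left out, among them all those named above. The count was 491, 541 and 701 without oligomycin replicates 2, 3 and 4, 489 and 2388 without pyrvinium replicates 2 and 3, 2047 with DESeq2, 856 with no filter and 3341 with the GC offset. With only the 8 libraries compared edgeR called 0 genes, with 2284 at an unadjusted p under 0.05, so the calls rest on the spread pooled over 16 libraries, from which limma-voom called 1115. Of the 15 named genes 13 kept their call with each library left out, while ATF4 lost it for 6 and TUBB2A for 4 of the 8 left-out libraries.

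Set against rotenone, pyrvinium had lower transcripts of mitochondrial DNA (11 of 13, median -3.31, list adjusted p = 7.17e-12, and adjusted p = 0.245 with an estimated correlation), MT-CYB at -3.99 ± 0.65. ATF4 targets were higher in 24 of 36 and lower in 1 (list adjusted p = 1.04e-16, and adjusted p = 0.190 with an estimated correlation), with 6.39 ± 1.03 for GDF15, 5.62 ± 0.54 for NUPR1 and 2.49 ± 0.51 for DDIT3. LAMP3 had 5.89 ± 0.60. NRF2 targets (11 of 23 higher, with ferritin FTH1 at 2.90 ± 0.51), autophagy and lysosome (7 of 31, with WIPI1 at 3.21 ± 0.43) and cell death (8 of 23, with BBC3 at 3.05 ± 0.44) were higher, with list adjusted p between 5.01e-08 and 3.05e-05 and adjusted p between 0.190 and 0.367 with an estimated correlation. Mitosis genes were lower in 16 of 36 (list adjusted p = 6.24e-16, and adjusted p = 0.249 with an estimated correlation), with -1.72 ± 0.26 for HJURP and -2.29 ± 0.41 for KIF20A. Replication histones were lower in 4 of 12 (list adjusted p = 5.27e-06, and adjusted p = 0.249 with an estimated correlation), with HIST1H2BC at -3.45 ± 0.37. GLDC and ADM were lower at -2.16 ± 0.28 and -2.11 ± 0.35. In ribosome biogenesis 5 of 34 were lower (list adjusted p = 3.62e-06, and adjusted p = 0.238 with an estimated correlation), with the nucleolar FBL at -0.85 ± 0.22.

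Pyrvinium and rotenone differed in 1565 genes, 905 higher with pyrvinium and 660 lower (57.8% higher, against 47.5% with library totals only and 38.0% with limma on log2(FPKM + 0.1)), and in 21 lists. Of the 20 reported here 16 were called with each library left out, among them all those named above. The count was 1660 with the replicate number as a block, used because residuals of these libraries matched by number. The labels name no pairs, and the signs of the GC slopes match by number too, so a pairing of the samples is not established. The count was 864 and 2486 without pyrvinium replicates 2 and 3, 898, 798 and 922 without rotenone replicates 1, 2 and 4, 392 with only the 8 libraries compared (1695 with the replicate block as well) and 3560 with the GC offset. Of the 14 named genes FBL lost its call without pyrvinium replicate 3 or rotenone replicate 1, 2 or 4.

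Oligomycin and rotenone, the 2 inhibitors of oxidative phosphorylation, differed in replication histones, with all 12 members lower with oligomycin than with rotenone and a median log2 fold change of -1.35 (list adjusted p = 4.30e-10, and adjusted p = 0.190 with an estimated correlation). HIST1H2BC was called over all genes, at -3.38 ± 0.37 (adjusted p = 9.34e-04), with 0.723 ± 0.185 against 7.56 ± 1.60 CPM (SD, n = 4), and 8 members adjusted over the list alone. Interferon response genes were called higher with oligomycin (list adjusted p = 2.34e-08, and adjusted p = 0.190 with an estimated correlation) and immediate early genes lower (list adjusted p = 1.13e-06, and adjusted p = 0.290 with an estimated correlation), with no member called over all genes. Lower with oligomycin were GLDC at -1.64 ± 0.27, ADM at -2.05 ± 0.35, the kinase NUAK2 at -1.68 ± 0.26 and CCRN4L, the deadenylase-like nocturnin, at -1.76 ± 0.26. Higher were TPP1, a lysosomal peptidase, at 1.62 ± 0.25, NCSTN, a subunit of γ-secretase, at 1.10 ± 0.18, its substrate APP at 1.04 ± 0.17 and the actin-severing GSN at 1.53 ± 0.28 (adjusted p between 0.0210 and 0.0431).

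Oligomycin and rotenone differed in 15 genes, 5 higher with oligomycin and 10 lower (33.3% higher, against 66.9% of the 441 genes with the GC offset), and in 17 lists, of which 10 were called with each library left out, among them the 3 named above and mitosis, lower with oligomycin (list adjusted p = 4.57e-06, and adjusted p = 0.458 with an estimated correlation). Of the others DNA replication was lower with oligomycin (list adjusted p = 0.0128, and adjusted p = 0.683 with an estimated correlation), and turned direction without oligomycin replicate 1 (median 0.06). The count was 3, 3, 2 and 1 without oligomycin replicates 1 to 4 and 1 without each rotenone replicate. It was 2 with the replicate number as a block, 242 with DESeq2, 63 and 108 with limma on log2 FPKM with pseudocounts of 0.1 and 1, and 133 with only the 8 libraries compared. Of the 9 named genes 1, HIST1H2BC, kept its call throughout.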

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

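Among the tests below, the GC offset, the other scalings, the nuclear respiratory lists, the S phase comparison and the count of calls with 1 library left out were chosen only after the result was seen, as was the correlation with GC slope. The splits, the thinning of counts and the single-library test of histones were set beforehand.

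In 17 of 223 groups of 4 libraries (7.62%, where chance gives about 1 in 20) 1 library lay far from the other 3. Pyrvinium replicate 1 had 32.5 M counts against 25.2 to 25.8 M in the other 3. Rotenone replicate 4 had 2.61% of counts on mitochondrial DNA (95% Wilson interval 2.60 to 2.62%) against 1.63 to 1.65%, ATF4 at 393 against 195 to 215 CPM, and NUAK2 at 10.3 against 13.2 to 13.7 CPM. DMSO replicate 1 was highest for SESN2 at 47.5 CPM (others at most 29.9), SQSTM1 at 239.9 (193), VEGFA at 85.2 (44.2), TRIB3 at 71.5 (38.6) and PDIA4 at 605.5 (517.5), which makes 5 of the 6 DMSO cases. DMSO replicate 2 was lowest for ELAVL1, at 192.5 against 209 to 210 CPM. Pyrvinium replicate 3 had MCM2 at 232 against 90.5 to 112.5 CPM. Oligomycin replicate 1 was lowest for GINS2 at 11.8 (others at least 48.0) and TGFBI at 17.7 (22.5), replicate 2 highest for AFAP1L2 at 13.04 (4.73) and replicate 4 highest for NCSTN at 133.1 CPM (110). Rotenone replicate 2 was highest for ATF3 at 55.5 (37.2) and replicate 1 for IFITM1 at 13.9 CPM (6.78).

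Transcripts of mitochondrial DNA were lower with pyrvinium, by a median of -4.03. GC content and scaling are argued against as the whole cause, since the median was -4.24 with the GC offset and at most -3.91 under 3 other scalings. A loss of equal size in respiratory chain transcripts of both genomes is argued against too. The lowest median of the nuclear lists was -0.809 and all 74 nuclear members lay above the median of the 13 genes. A smaller nuclear loss is not argued against. These nuclear lists were called lower with the preset correlation (list adjusted p between 1.29e-07 and 7.42e-06), though not with an estimated one. Within groups the log2 share of mitochondrial DNA fell with the GC slope of the library (Pearson's r -0.80, permutation p = 0.00159, and -0.66 without pyrvinium replicates 1 and 4), while the mean GC slopes of DMSO and pyrvinium were 0.002 and 0.015. A candidate explanation is that pyrvinium lowers transcription of mitochondrial DNA or its copy number, and these were not measured.

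More genes were called for pyrvinium than for oligomycin or rotenone. Depth and GC content are argued against, with 2680 calls for pyrvinium, 40 for oligomycin and 133 for rotenone at 23.7 M counts each, and 4836, 263 and 615 with the GC offset. A single library is argued against, since the lowest count for pyrvinium with 1 library left out was 1712. With only the 8 libraries compared the counts were 1103, 70 and 525, so the size of the excess depends on the spread pooled over 16 libraries. The pattern may be biological, and as only 1 dose of each compound was used, potency and dose stay open.

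Replication histones were higher with rotenone than with oligomycin. With the GC offset the list had an adjusted p of 6.66e-08, and the highest with 1 library left out was 2e-08 (4.30e-10 in the main test, 0.19 with an estimated correlation), which argues against GC content and a single library. More cells in S phase with rotenone stays open: against DMSO the DNA replication list had a median of -0.23, the other direction, with an adjusted p of 0.00426 and of 0.64 with an estimated correlation. Set directly against rotenone, oligomycin had lower lists of DNA replication (median -0.19, adjusted p = 0.0128, 0.683 with an estimated correlation) and mitosis (-0.56, 4.57e-06, 0.458). The first goes with more cells in S phase, but rests on 1 library, as it turned direction without oligomycin replicate 1. The mitosis difference was called with each library left out, but that list does not measure S phase. With rotenone against DMSO mitosis was not called (list adjusted p = 0.516). Histones also did not follow DNA replication in pyrvinium against oligomycin. There DNA replication was lower (list adjusted p = 1.24e-16) while histones did not pass (list adjusted p = 0.701, median 0.03). As background, several of these histone genes give polyadenylated transcripts in cells that leave the cycle, so a change in polyadenylation may contribute.

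Other splits of the same libraries were set against the real grouping, with a limit of under 0.05 of the splits set beforehand. For counts of genes 1 of 35 splits, the real one, was as large in pyrvinium against DMSO (2716, highest other 1350), oligomycin against DMSO (51, 0) and rotenone against DMSO (159, 0). The same held in pyrvinium against oligomycin (1288, 709) and oligomycin against rotenone (15, 0). These counts pass the limit, but 1 of 35 is the smallest share such splits can give. It was not adjusted over the tests, and the splits kept the other 8 libraries in the fit, so chance is not excluded. For counts of lists, adjusted within 1 comparison, the real split alone of 35 was as large in pyrvinium against DMSO (27, highest other 24), oligomycin against DMSO (25, 21) and pyrvinium against oligomycin (21, 20). Other splits came close to these counts, so the number of lists called with the preset correlation says little by itself. The limit was not met for lists in rotenone against DMSO (19, highest other 26, with 4 of 35 as large) or oligomycin against rotenone (16, 20, with 9 of 35). Pyrvinium and rotenone libraries matched by number in their residuals, and the 8 splits that part all such pairs are too few for a share under 0.05 (genes 1565, highest other 0, and lists 21, highest other 21 with 2 of 8 as large). Of all 35 splits there, 2 were as large for genes and 2 for lists, the real one included in each. The limit set beforehand on the splits was therefore not met for this comparison. For genes the other split, replicates 1 and 2 of both compounds against replicates 3 and 4, gave 3540. That points to a structure of the samples that follows replicate number and the sign of the GC slope. With the replicate block that comparison gave 1660 genes.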

How the results depend on the processing

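The alternatives for GC content, and the block on only the 8 libraries of P-R, were chosen only after the result was seen. The others were set beforehand, while the use of scalings and left-out libraries to weigh explanations came later. Where no cause is given below, the cause was not tested. Counts are genes called, and the comparisons are written P-D, O-D, R-D, P-O, P-R and O-R, from pyrvinium, oligomycin, rotenone and DMSO. Series of 6 values follow this order.

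RLE scaling, scaling without genes of mitochondrial DNA, library totals only and the filter of at least 10 counts kept each count of genes within 1.5 times. DESeq2 gave 228 (O-D), 455 (R-D), 2047 (P-O) and 242 (O-R) genes, limma-voom 21 (O-D) and no filter 856 (P-O). Limma on log2 FPKM gave 63 (O-R) with a pseudocount of 0.1, and 29 (O-D), 246 (R-D) and 108 (O-R) with 1. With the replicate block O-R gave 2. With only the 8 libraries compared, where these alone estimate the spread, edgeR gave 1103 (P-D), 525 (R-D), 392 (P-R, 1695 with the replicate block as well) and 133 (O-R). For P-O it gave 0, with 2284 genes at an unadjusted p under 0.05, where limma-voom on 16 libraries gave 1115. Counts fell in each comparison with pyrvinium and rose in R-D, O-R and O-D (70), so fewer samples are not the whole cause. The GC slopes had an SD of 0.68 in pyrvinium and of 0.24 to 0.38 in the other groups. Whether the pooled spread is too small for pyrvinium was not tested.

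The GC offset gave 4836, 263, 615, 3341, 3560 and 441 genes, holding 2682 of the 2716 calls for pyrvinium, 51 of 51 for oligomycin and 156 of 159 for rotenone against DMSO. The GC slope as a covariate gave 5724, 437, 901, 4166, 4216 and 815, and the GC offset with the replicate block 5144, 304, 680, 3588, 3830 and 562. Without the 3 libraries of steepest GC slope oligomycin and rotenone gave 161 and 240 against DMSO.

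With 1 library left out, which also lowers the number of samples, the counts ranged from 1712 to 3466, 0 to 73, 38 to 98, 489 to 2388, 798 to 2486 and 1 to 3. The 0 for oligomycin came in edgeR without DMSO replicate 2, 3 or 4, with 1105, 1087 and 1207 genes at an unadjusted p under 0.05. Correlations ranged from 0.44 to 0.62 for pyrvinium and oligomycin, 0.44 to 0.58 for pyrvinium and rotenone and 0.46 to 0.62 for oligomycin and rotenone. With DMSO split between the compounds they averaged 0.35, 0.32 and 0.23, and with DMSO shared the first was 0.62 among genes of at least 5 CPM.

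Lists called fell to 1, 1, 2, 0, 0 and 0 with an estimated correlation in camera, and fry gave 5 (O-D), 10 (R-D), 13 (P-O) and 3 (O-R). Genes called alike by all 3 compounds numbered 83 with DESeq2 and 88 with the GC offset. Without DMSO replicate 2, 3 or 4 oligomycin had 0 calls, so no gene could be called alike.

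The fall of the mitochondrial DNA share with pyrvinium, -2.51 points, had p = 0.125 with the replicate block, the smallest that 4 exact sign flips can give. The difference for oligomycin ranged from -0.87 to 0.77 with 1 library left out. Among uncalled genes of pyrvinium against DMSO, MYC turned to -0.087 without the libraries of steepest GC slope, and TFAM to 0.0151 and VIM to 0.0152 with library totals only. With 1 library left out AXIN2 ranged from -0.71 to 0.20, MYC from -0.013 to 0.19, TFAM from -0.47 to 0.36 and VIM from -0.44 to 0.24.

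Mitochondrial rRNA and tRNA were not analysed here, so the share over all mitochondrial genes was not run, and neither was a split of DMSO for calls shared by 3 compounds, as 4 libraries cannot be dealt out 2 to each of 3 compounds. With all libraries thinned to 23.7 M counts the calls were 2680, 40 and 133 against DMSO, where the full counts gave 2716, 51 and 159. Oligomycin and rotenone libraries held only 23.7 to 27.7 M counts before thinning. The thinning thus tests unequal depth and cannot show what deeper libraries would call. A floor of 3 counts lay at 0.0725 to 0.127 CPM per library and covers counting error only.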

Other observations

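The lists of fibroblast and endothelial markers were set beforehand and tested. The single markers here were picked after the data were seen and are given with no test, as CPM over library totals without TMM scaling. Immune markers CD3E, CD3D and MS4A1 were at 0 in all 16 libraries and PTPRC had a mean of 0.00787 CPM in DMSO (n = 4). CD14 had a mean of 4.24 CPM in DMSO and 0.601 with pyrvinium, and LYZ of 1.57 CPM in DMSO. ITGAX had 0.0798 CPM in DMSO and 1.17 with pyrvinium, ITGAM 0.0726 and 1.29 with rotenone, and endothelial ROBO4 9.41 and 38.7 with pyrvinium. Of fibroblast genes COL1A2 had a mean of 702 CPM and COL3A1 of 52.7 CPM in DMSO, while COL1A1 had 1.35 CPM and DCN and LUM had 0.0532 and 0.069 CPM.

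Of the 4 pyrvinium libraries replicate 3 lay nearest the DMSO mean in 1425 of the 2716 called genes, 23 of 33 called ATF4 members and 28 of 33 called DNA replication members. Of the 4 oligomycin libraries replicate 2 did in 39 of 51 called genes. Examples for pyrvinium replicate 3, chosen after their values were seen, were NUPR1 at 11.1 against 51.9 to 69.0 CPM and DDIT3 at 9.42 against 48.4 to 102 CPM in the other 3 libraries. Without pyrvinium replicate 3, pyrvinium against DMSO gave 3466 genes, pyrvinium against oligomycin 2388 genes and pyrvinium against rotenone 2486.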
